A study of Caenorhabditis elegans with 2 samples.

How the data were processed

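Binding of the tagged transcription factor FKH-4 was measured by ChIP-seq in 2 samples of whole L1 larvae, which the labels describe as biological replicates 1 and 2 of 1 strain and stage. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP. The sample listings deposited with the data state that each replicate's peak list was made against a control, which belongs to another experiment and is not analysed here. They also state that the IDR set was derived from the lists of replicate 1, replicate 2 and both pooled. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. All lists were deposited by the authors in a ce10 and a ce11 version.

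The signal value that the authors deposited for each peak is never negative, and its scale and normalisation are not given in the sources used here, so it was used only to rank and describe peaks within a list. The −log10 q values of the peaks, per the deposited files, ran from 2.2 to 3.3 in the IDR set and down to 0.0222 in the pooled relaxed list, and they entered no test. Relaxed lists hold many weak peaks by design, since they are the input to the IDR step. The pooled list and replicate 1's list each end at 30000 peaks, so their lower end is set by that number. All 1189 IDR peaks were also the 1189 peaks of highest signal in the pooled list. The alternative peak set made of the strongest pooled peaks was therefore identical to the main one, tests nothing and was not counted among the alternatives under which a call was kept. Most peaks share a fixed width (median 396 bp, and 400 bp in replicate 1), which follows from the peak calling, so widths were not compared. The ce10 list of replicate 1 holds 1 peak of 7000383 bp. It was left out of the ce10 overlap, and the ce11 lists have no peak wider than 1000 bp.

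Positions are on ce11, counted from 1. The reference assembly WBcel235 has the same chromosome lengths, and genes, transcripts and RNA classes came from its Ensembl annotation, release 115, with 19973 coding genes on the 6 nuclear chromosomes. The ce10 lists served only for peak counts and replicate agreement, and no coordinate was converted. A summit was in a promoter if it lay from 1000 bp upstream to 200 bp downstream of the TSS of any coding transcript. Remaining summits were placed in coding exons, UTRs, other gene body or intergenic sequence, in that order. A gene with at least 1 IDR summit in its window is called bound here, which does not show that the peak acts on that gene, since divergent genes share windows.

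Replicate agreement was the share of the strongest peaks of replicate 1 with a summit within 200 bp among as many of replicate 2, tested against 1000 circular shifts. The interval of the rank correlation came from 1000 bootstrap resamples of peaks. Promoter share was tested against 1000 random placements on the same chromosomes, and chromosome shares by exact binomial tests against chromosome length. The 32 gene lists and 10 RNA classes were tested by two-sided Fisher's exact tests, and 26 motifs by exact McNemar tests of windows of 50 bp on either side of the summit against flanks centred 300 bp away. Adjusted p is Benjamini-Hochberg within each family, with a threshold of 0.05. Intervals are 95% exact Clopper-Pearson intervals and cover counting error only. Tests treat peaks and genes as independent although neighbours are not, and they describe these 2 libraries, not a wider set of animals. Lists, motifs, tests and the settings to vary were fixed before the data were examined. Lists defined by name patterns take in some unrelated genes, so 2 lists were also run with strict names, which left out 3 and 56 genes. Of the genes listed by name, 3 were absent from the annotation.

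The genes named are fkh-4 and unc-119, the genes nearest to the 20 strongest IDR peaks, up to 3 bound members of each list with the strongest peaks, and the bound forkhead and Hox genes. Sequence names were counted instead of named. The SL2 RNA genes in the closing observations were named after their values were seen. The settings varied were the match distance, the number and source of peaks, the promoter window, the background, the assignment of peaks to genes, and the motif window and flank, and each replicate was left out in turn. Leaving out a replicate meant taking the 1189 strongest peaks of the other replicate's own list. Assignment to the nearest TSS used every IDR peak at any distance, including those outside promoter windows. It therefore changed the peaks that count as well as their genes, with 1071 genes bound against 956. Other alternatives were chosen after seeing the data. They were strict family names, IDR peaks matched in both replicates, and IDR peaks without the 14-base element described in the closing observations.

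The element was found as the 14-base word present within 100 bp of the most IDR summits, and copies with at most 1 mismatch were counted. For the test on separate chromosomes the word was chosen again from the peaks of I, II and III and its promoter copies were scored on IV, V and X, and the reverse. A word of 36 bases was called unique if it occurs once on both strands of the nuclear genome. Windows matched to the gap at fkh-4 had the same width, a GC content within 2 percentage points and within 2 of its number of coding TSS, in steps of 1000 bp. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

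The tests were tested on simulated data. Of 20 simulated lists among 19973 genes planted with more bound genes, 18 were recovered, and 1 of 20 lists with no planted difference was called. These lists were drawn at random with independent genes. The planted effect was stronger than that found for heat shock, body wall muscle, respiratory chain, cell cycle, Wnt and proteasome genes. Both rates may therefore differ for such lists and for neighbouring genes that share peaks. A replicate overlap planted at 47.6% over 1189 peaks was found as 47.9%. A motif planted in 1189 simulated windows was recovered with 0 of 25 other motifs called, and 4 of 2079 other words of 6 bases were called. The simulated summit and flank windows had the same base composition, whereas the real ones differed (43.97% against 35.8% G and C). These counts therefore do not measure calls that arise from that difference. Of 20 random sets of 1189 peaks, 1 passed the promoter threshold.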

Results

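FKH-4, a forkhead-family transcription factor of the nematode Caenorhabditis elegans, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hermaphrodite larvae of the first stage (L1). The strain, OP100, carries FKH-4 fused at its C terminus to GFP and FLAG in a transgene, in an unc-119 mutant background. The larvae were starved after bleaching to synchronise them and collected 6 h later, and an antibody against GFP was used. The 2 samples form 1 group of 2 biological replicates, so the comparisons made here are between the replicates and between the peaks and the genome. No control sample is among the 2 samples, and read depth is not given in the sources used here. On the ce11 build, the authors' reproducible peak set (IDR, irreproducible discovery rate) held 1189 peaks, made from both replicates. The longer relaxed lists held 30000 peaks for the pooled reads, 30000 for replicate 1 and 22442 for replicate 2. Peak signal values are the authors' own. They ran from 51.7 to 645 in the IDR set (median 80.4), up to 221 in replicate 1 and up to 423 in replicate 2, and are comparable within a list only.

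Most of the strongest FKH-4 peaks of replicate 1 were also among the strongest of replicate 2, and the order of the shared peaks was partly the same. Of the 1189 strongest peaks of replicate 1, 776 (65.3%) had a summit within 200 bp among the 1189 strongest of replicate 2. Circular shifts of replicate 2's peaks along the chromosomes gave 0.479% on average and 1.18% at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The IDR set was itself derived from both replicates' lists and the pooled list, and its members are the 1189 strongest pooled peaks. The values that follow therefore describe that set and are no test of agreement. Each of the 20 strongest IDR peaks lay among the 100 strongest peaks of each replicate. In the whole relaxed lists, 1171 IDR peaks (98.5%) had a summit within 200 bp in replicate 1 and 1188 (99.9%) in replicate 2. Across the 1170 IDR peaks found in both, Spearman's rho of the signal values was 0.593 (95% bootstrap interval 0.549 to 0.631), a correlation across peaks, which are not independent replicates. The 413 peaks of replicate 1 without a match lay less often in promoters than the 776 matched ones, 47.0% against 61.3% (p = 2.21e-06, two-sided Fisher's exact test). This difference did not pass the threshold among the 594 strongest peaks (58.6% against 64.8%, exact p = 0.178). The 417 unmatched peaks of replicate 2 showed 57.6% against 61.4% (exact p = 0.215). Of replicate 1's unmatched peaks, 75.3% met a weaker peak of replicate 2's relaxed list, against at most 13.3% under 1000 shifts.

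**Figure D1:**
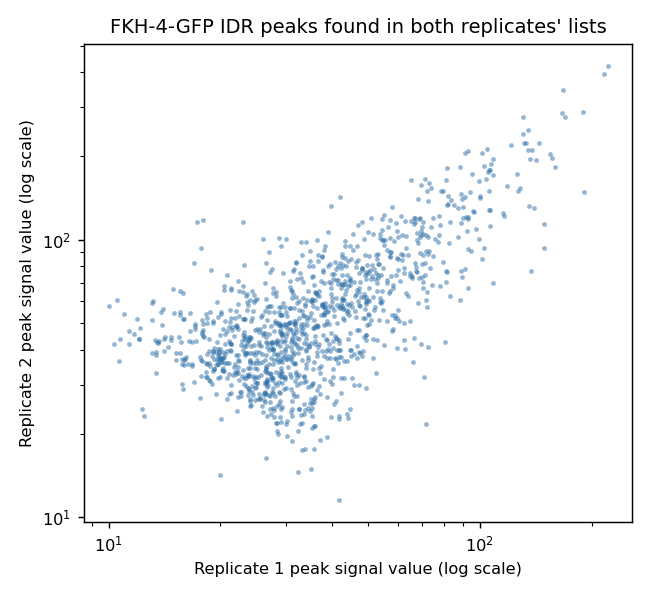
Signal values of the 1170 IDR peaks found in both replicates' lists, with replicate 1 on the horizontal axis and replicate 2 on the vertical axis, both on log scales in the authors' signal units. Each point is 1 peak; the order of the peaks was partly shared (Spearman's rho 0.593).

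FKH-4 peaks lay mainly just upstream of protein-coding genes. Of the 1189 IDR summits, 699 (58.8%, 95% exact interval 55.9 to 61.6) fell from 1000 bp upstream to 200 bp downstream of a coding transcription start site (TSS), where 26.0% were expected from random placement (two-sided p = 0.002, the smallest that 1000 placements can give). The median promoter summit was 191 bp upstream of the nearest TSS. Coding exons held 27 summits (2.27%) although coding exons outside promoter windows make up 18.9% of the genome, and introns and other gene-body sequence held 165 (13.9% against 27.2%). Intergenic sequence held 281 (23.6% against 25.04%). Chromosome III held more peaks than its length predicts, with 229 peaks or 19.3% (17.05 to 21.6) against 13.7% (adjusted p = 7.78e-07, exact binomial test over 6 chromosomes). Chromosome I was also above its share (17.6% against 15.03%, exact adjusted p = 0.0249), and IV and V were below theirs (14.5% against 17.4%, adjusted p = 0.0132; 16.7% against 20.9%, adjusted p = 0.0011). The X chromosome, which carries fkh-4 itself, held 213 peaks, 17.9% against 17.7% of the genome length (exact p = 0.82). Measured against its 13.7% of coding genes, X was above its share (exact adjusted p = 8.18e-05) and II below its share (14.05% against 17.3%, 0.0037). Among the 594 strongest peaks chromosome III kept its call (exact adjusted p = 0.002), and I, IV and V lost theirs (0.342, 0.396 and 0.342). The call for I was also lost without replicate 2 (exact adjusted p = 0.0637) and that for IV against the share of coding genes (0.0717).

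The strongest peak stood at the start of cux-7 on chromosome III, with its summit at 7520849 and a signal of 645. It lay 4 bp upstream of the cux-7 TSS and also in the promoter window of lig-4, which encodes a DNA ligase. Of the 20 strongest peaks, 17 were in promoters, 2 were intergenic and 1 was inside a gene. After cux-7, the named genes nearest to them were lrpr-1 (V, summit 5917912, signal 406), thoc-5 of the THO mRNA export complex (III, 5349461, 385) and the prolyl isomerase gene pinn-1 (II, 2889396, 377). Next came sco-1, a cytochrome oxidase assembly factor (II, 4299444, 360), ced-5, which acts in the engulfment of dying cells (IV, 10483917, 355), and the translation initiation factor gene eif-3.B (II, 14795156, 353). The ribosomal protein gene rpl-35 (III, 7854686, 338) and the cyclophilin gene cyn-10 (II, 6913511, 337) completed them. The other 11 nearest genes are known by sequence names.

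Genes of the protein synthesis and folding machinery carried FKH-4 promoter peaks far more often than other genes. In all, 956 of 19973 coding genes (4.79%) had an IDR summit in their promoter window, and 275 of the 699 promoter peaks (39.3%) lay in the windows of 2 or more genes. Among ribosomal protein genes, 37 of 81 (45.7%, 34.6 to 57.1) had a peak, against 4.62% of other genes (odds ratio 17.4, adjusted p = 4.96e-26, two-sided Fisher's exact test over 32 lists). The strongest were rpl-35, rpl-3 (III, summit 3867562, 292 bp upstream of the TSS, signal 274) and rpl-12 (IV, 13240687, signal 243). The list as written takes in 3 rpa genes, which are not ribosomal protein genes; without them 36 of 78 were bound (exact adjusted p = 1.61e-25). Assignment of each peak only to the gene with the nearest TSS left 21 of 81 bound and lowered the odds ratio to 6.28 (exact adjusted p = 1.71e-08). A background of genes with any pooled peak lowered the odds ratio to 7.81 (exact adjusted p = 1.32e-14). Translation factors followed with 12 of 43 (27.9%, exact adjusted p = 5.58e-06), led by eif-3.B, the mitochondrial elongation factor gene tufm-2 (I, 4247594, signal 184) and iff-2 (II, 8561457, 109); their odds ratio of 7.79 fell to 4.06 with the nearest TSS. Heat shock proteins and their co-chaperones had 11 of 52 (21.2%, exact adjusted p = 1.51e-04), led by the chaperone genes hsp-90 (V, 14685757, 351), hsp-60 (III, 1619118, 234.9) and hsp-1 (IV, 17278499, 155). The hsp-90 summit lay inside the gene, 403 bp upstream of an internal TSS, and nearer to the TSS of another gene.

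Genes of respiration, body wall muscle, the cell cycle, Wnt signalling and the proteasome were also bound above background. Of 52 respiratory chain genes, 9 had a peak (17.3%, exact adjusted p = 0.0029), among them the oxidase subunit gene cox-5A (III, 12905199, signal 238), atp-5 (V, 11124141, 140) and isp-1 (IV, 8136775, 115.4). Body wall muscle markers had 11 of 49 (22.4%, 11.8 to 36.6, odds ratio 5.81, exact adjusted p = 9.97e-05). They were led by the calponin-like gene cpn-3 (I, 3987278, 173), the giant sarcomere protein gene unc-89 (I, 4080546, 109) and the troponin I gene tni-3 (V, 16835168, 90.9). The unc-89 summit lay inside the gene, beside an internal TSS. Cell cycle and DNA replication genes had 7 of 44 (15.9%, exact adjusted p = 0.0163), with the replication clamp gene pcn-1 (IV, 4049732, 187), the retinoblastoma homologue lin-35 (I, 5807438, 160) and its E2F partner efl-1 (V, 16965862, 105). The Wnt pathway had 5 of 26 (19.2%, exact adjusted p = 0.0205), with the beta-catenin gene wrm-1 (III, 5722068, 217) and the Dishevelled genes mig-5 (II, 8185202, 186) and dsh-1 (II, 5220829, 113). The dsh-1 summit lay inside the gene, 118 bp upstream of an internal TSS. Proteasome subunits had 5 of 33 (15.2%, exact adjusted p = 0.0443), with rpn-3 (III, 8447141, 98.8), rpn-11 (II, 4044568, 97.7) and pas-4 (I, 8728683, 73.2). The rpn-3 peak is also counted for a gene of the heat shock list. Among the 594 strongest peaks these 5 calls were lost (adjusted p from 0.117 to 0.483). Odds ratios moved from 4.76 to 4.68 for Wnt, 3.78 to 3.59 for the cell cycle, 4.19 to 2.99 for respiration, 5.81 to 3.19 for muscle and 3.57 to 2.31 for the proteasome. Under shifts of the bound state along the gene order, the Wnt and proteasome calls were lost (permutation adjusted p = 0.0501 and 0.0983). Without replicate 2 the Wnt call was lost (odds ratio 2.75, exact adjusted p = 0.229), as it was without the peaks that hold a shared 14-base element, among them that of wrm-1 (4 of 26, 0.0599). Assignment to the nearest TSS, which also counts peaks outside promoter windows, raised Wnt to 8 of 26 (odds ratio 7.90, exact adjusted p = 2.33e-04). The cell cycle call was lost without replicate 1 (odds ratio 2.50, exact adjusted p = 0.133). The proteasome call was lost without replicate 1 (odds ratio 3.48, exact adjusted p = 0.0519) and without replicate 2 (2.91, 0.149). The respiratory, cell cycle and proteasome calls were also lost when each peak went only to the gene with the nearest TSS (exact adjusted p = 0.555, 0.209 and 0.213), while muscle kept its call there with 13 of 49 (1.03e-05). Against only the genes with any pooled peak, muscle kept its call at a lower odds ratio of 2.99 (28.2% against 11.6%, exact adjusted p = 0.016) and the other 4 lists lost theirs (0.122 to 0.383). With the narrower promoter window the cell cycle, Wnt and proteasome calls were lost (exact adjusted p = 0.0716, 0.0502 and 0.0859), at odds ratios of 3.27, 4.64 and 3.52. With the wider window the proteasome call was lost (odds ratio 2.64, exact adjusted p = 0.111).

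**Figure D2:**
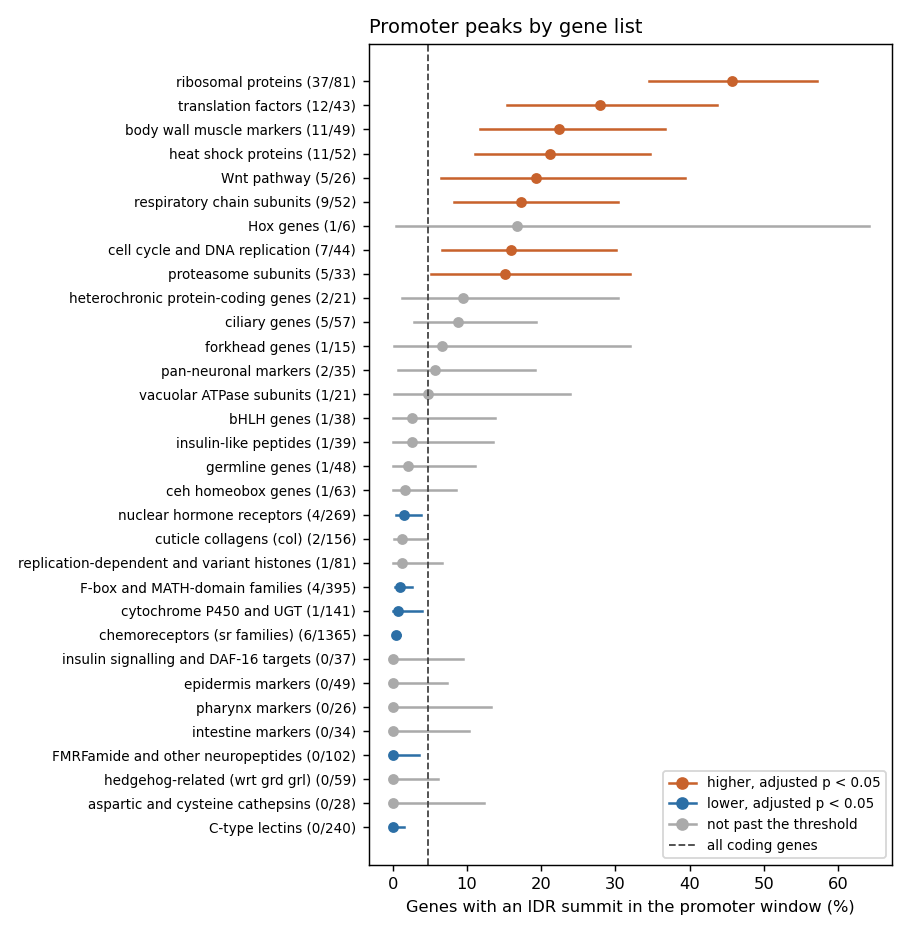
Share of genes with an IDR summit in the promoter window (horizontal axis, percent) for each of 32 gene lists, with bound and total members in brackets, points for the share and lines for 95% exact intervals. The dashed line marks all coding genes (4.79%); ribosomal proteins stand highest at 45.7%, and 14 lists passed the threshold, 8 above and 6 below.

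Chemoreceptor genes and 5 other lists carried FKH-4 promoter peaks less often than other genes. Chemoreceptor genes had 6 of 1365 (0.44%, 0.161 to 0.954; odds ratio 0.0821, exact adjusted p = 5.80e-21), and the strongest of them, at srgp-1 (IV, 11569982, signal 135), belongs to a gene that is not a chemoreceptor. The next were srd-3 (II, 129989, 97.1) and sri-5 (I, 11182524, 85.5). Without replicate 1, 3 of 1365 were bound (odds ratio 0.0399), and without replicate 2, 7 of 1365 (0.102). With strict family names 4 of 1309 were bound (exact adjusted p = 3.68e-22). C-type lectins had 0 of 240 (up to 1.53%, exact adjusted p = 9.34e-05). F-box and MATH-domain genes had 4 of 395 (1.01%, exact adjusted p = 2.89e-04), of which fbxb-85, fbxa-90 and fbxc-23 had signals of 116, 105 and 60.02, and with the narrower promoter window 2 of 395 were bound. The fbxa-90 peak is also counted for efl-1 among the cell cycle genes. Nuclear hormone receptors had 4 of 269 (1.49%, exact adjusted p = 0.019), led by nhr-47, nhr-142 and nhr-196 with signals of 69.9, 67.4 and 62.0. The nhr-47 peak is also counted for a gene of the heat shock list. Detoxification genes of the cytochrome P450 and UGT families had 1 of 141 (exact adjusted p = 0.0399), cyp-33C12, and neuropeptide genes 0 of 102 (up to 3.55%, adjusted p = 0.0399). The last 3 calls were lost when the bound state was shifted along the gene order, with permutation adjusted p of 0.0513, 0.0828 and 0.0501. Assignment to the nearest TSS also ended the calls for nuclear hormone receptors (14 of 269, exact adjusted p = 1) and neuropeptides (3 of 102, adjusted p = 0.555). That assignment also counts peaks outside promoter windows. Without replicate 2 the calls for neuropeptides (2 of 102) and for P450 and UGT genes were lost (exact adjusted p = 0.533 and 0.0662). The narrower and the wider promoter window ended the calls for nuclear hormone receptors (exact adjusted p = 0.117 and 0.055) and neuropeptides (0.0859 and 0.055). Among the 594 strongest peaks and against genes with any pooled peak, the calls for P450 and UGT genes (exact adjusted p = 0.437 and 0.289) and neuropeptides (0.319 and 0.105) were lost. Both calls were also lost without the element's peaks (exact adjusted p = 0.077 and 0.0599). Neither list lost a bound gene there, since the cyp-33C12 peak does not hold the element. The bound share of all coding genes fell from 4.79% to 4.33%.

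Tissue marker lists other than body wall muscle did not pass the threshold, and small lists leave wide intervals. Intestine had 0 of 34 (up to 10.3%), pharynx 0 of 26 (up to 13.2%), epidermis 0 of 49 (up to 7.25%) and pan-neuronal markers 2 of 35, at the synaptic genes snb-1 and syd-2 (V, 6657034, signal 57.9; X, 10555743, 54.4), or 5 of 35 with the wider promoter window. Ciliary genes had 5 of 57, led by tmem-107, klp-11 and ift-43, and germline genes 1 of 48, at spn-4. The tmem-107 peak is also counted for a ribosomal protein gene. Hedgehog-related genes had 0 of 59, insulin signalling and DAF-16 target genes 0 of 37, and cathepsins 0 of 28. Of the insulin-like peptides 1 of 39 was bound, ins-39. Cuticle collagens had 2 of 156, col-71 and col-38 (exact adjusted p = 0.0772), histones 1 of 81, his-37, and vacuolar ATPase subunits 1 of 21, vha-8. The col-38 peak is also counted for a ribosomal protein gene. Among transcription factors, 1 of 15 forkhead genes was bound, fkh-9 (X, summit 3819071, signal 72.2). Its summit lay inside the gene, 583 bp upstream of an internal TSS. Of the Hox genes 1 of 6 was bound, mab-5 (III, 7784428, 974 bp upstream of the TSS, signal 78.6). Neither list had a bound gene with the narrower promoter window or among the 594 strongest peaks. Without replicate 2 no forkhead gene was bound, and with the nearest TSS, peaks outside promoter windows included, 3 of 15 were. The ceh homeobox genes had 1 of 63, ceh-38, and bHLH genes 1 of 38, hlh-11. Heterochronic genes, which time larval development, had 2 of 21, nhl-2 (III, 4899917, signal 221) and lin-28 (I, 8410081, 55.4). The lin-28 summit lay inside the gene, 161 bp upstream of an internal TSS. None of these lists passed the threshold.

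FKH-4 peaks also lay at the 5' ends of small nuclear and small nucleolar RNA genes. Within 200 bp of the gene start, 22 of 346 snoRNA genes (6.36%, 4.03 to 9.47) had an IDR summit, against 1.91% of coding genes (odds ratio 3.49, adjusted p = 6.00e-06, two-sided Fisher's exact test over 10 classes). Of the snRNA genes, 9 of 129 did (6.98%, odds ratio 3.86, exact adjusted p = 0.0024). Of these genes, 12 snoRNA and 6 snRNA genes had a peak that also lay in a coding promoter window. The snoRNA call was lost among the 594 strongest peaks (exact adjusted p = 0.288), and the snRNA call with a window of 500 bp (adjusted p = 0.0732). Genes for tRNA had 18 of 612 (2.94%, exact adjusted p = 0.146). Genes for piRNA, short germline RNAs that silence foreign sequence, had 15 of 15363 (0.0976%, exact adjusted p = 2.56e-73), and pseudogenes 4 of 2128 (0.188%, adjusted p = 1.31e-11).

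The forkhead consensus was not more frequent at FKH-4 summits than beside them. RTAAAYA, the core that many forkhead proteins bind, occurred within 50 bp of 76 summits (6.39%) and in 126 flanks of the same size centred 300 bp away (10.6%; adjusted p = 0.0011, two-sided exact McNemar test over 26 motifs). Summit windows were richer in G and C, at 43.97% against 35.8%, and dinucleotide-preserving shuffles of the same windows held the core in 5.55%, a difference of 0.841 percentage points the other way (exact adjusted p = 0.55). The variant GTAAACA occurred at 1.01% of summits and in 1.18% of flanks (exact adjusted p = 0.879). GACGC, an alternative site of some forkhead proteins, occurred at 21.4% of summits and in 6.98% of flanks (exact adjusted p = 3.14e-23), and in 15.7% of the shuffles (adjusted p = 7.35e-04). CTGCGTCT, listed as a ribosomal motif, contains GACGC on its other strand. It rose from 0.841% of flanks to 6.73% of summits (exact adjusted p = 1.98e-14), against 0.252% of the shuffles. Every window with CTGCGTCT also holds GACGC, so their calls are not separate. GACGC stood in 254 summit windows against 187 shuffles, and CTGCGTCT in 80 against 3. GACGC outside CTGCGTCT was not tested, so its call does not show forkhead-type binding. The E-boxes CACGTG (4.46% against 1.85%) and CAGCTG (4.63% against 2.02%) and the C-rich site YYCCYCC (10.1% against 5.05%) were also more frequent at summits, with adjusted p of 6.31e-04, 0.0014 and 1.39e-05. WGATAA, the site of GATA factors, was less frequent (6.90% against 15.1%, exact adjusted p = 1.37e-09), also against shuffles (13.1%). In all, 17 of 26 motifs passed the threshold, 8 higher and 9 lower at summits, and against shuffles 9 were higher and 2 lower. Of 2080 words of 6 bases tested as a separate family, 563 passed the threshold, led by CGAGAG (14.5% against 2.44%, exact adjusted p = 1.47e-23). Of these, 342 were more and 221 less frequent at summits. The words were not compared with shuffles, so these counts may reflect the difference in base composition. CGAGAG also lies in the 14-base element of the closing observations, on its other strand.

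**Figure D3:**
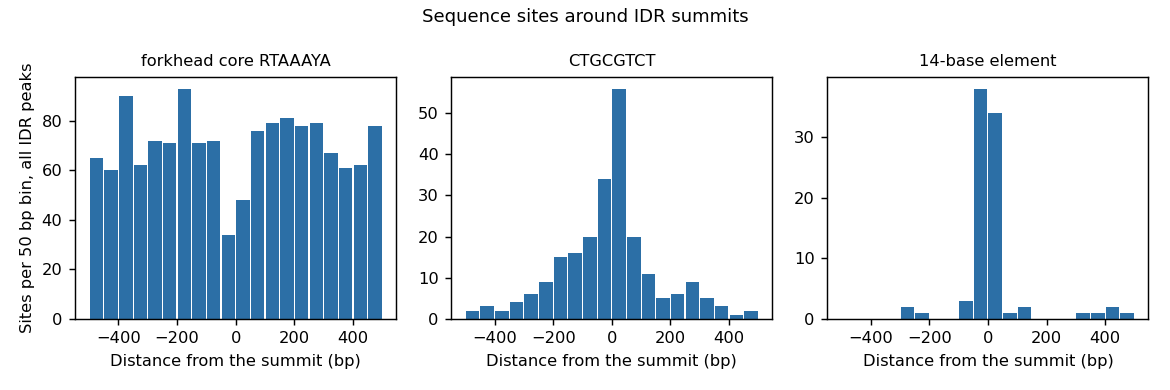
Number of sites per 50 bp bin (vertical axes) by distance from the summit in bp (horizontal axes), summed over all 1189 IDR peaks, for the forkhead core RTAAAYA, the site CTGCGTCT and the 14-base element GTACTCCTCTCGGA with at most 1 mismatch. The forkhead core dips to 34 sites in the bin just before the summit; the element and CTGCGTCT are most frequent within 50 bp of the summit.

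The tagged gene itself lay in a stretch without peaks. Gene fkh-4 spans X 13427114 to 13428855 on the minus strand, and no IDR peak or pooled relaxed peak had its summit within 20 kb of it. The lack of an IDR peak is not unusual. The IDR gap there was 117800 bp, and 62.1% of the genome lies in IDR gaps as wide. The pooled list had no summit between X 13396766 and 13448918, a gap of 52152 bp against a median gap of 2082 bp, and the gap ranked 7 among 29994. The gap around the gene was 43500 bp in replicate 1 and 52137 bp in replicate 2. Within 20 kb of fkh-4, replicate 1 had 0.479 relaxed summits per 10 kb and replicate 2 had 0.24, against genome means of 2.99 and 2.24. The gene mutated in the strain, unc-119 (III 10902641 to 10908935), is also carried with the tagged fkh-4 as a rescue. In the IDR set, 56.5% of the genome lies in gaps as wide as that around unc-119. No IDR peak lay within 20 kb of it. The pooled list and replicates 1 and 2 had 4.75, 3.67 and 3.46 relaxed summits per 10 kb there, above genome means of 2.99, 2.99 and 2.24.

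**Figure D4:**
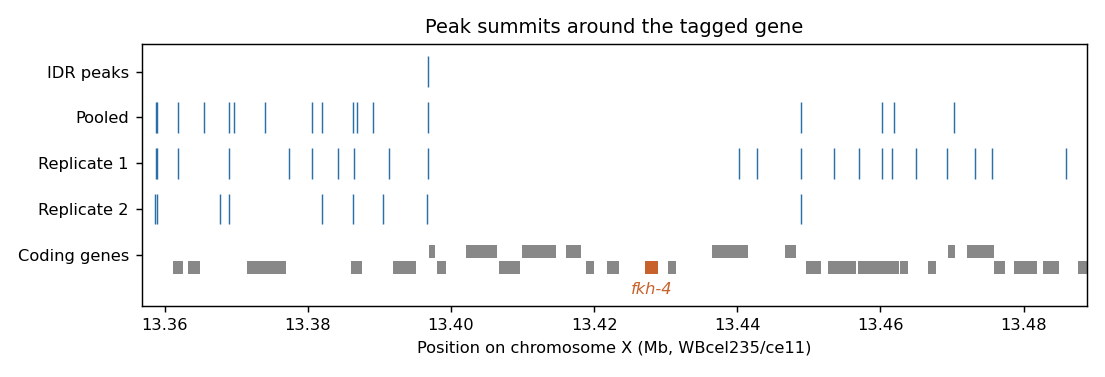
Peak summits (vertical lines) in the IDR set, the pooled relaxed list and the relaxed lists of replicates 1 and 2 along chromosome X in Mb, with coding genes below (upper row plus strand, lower row minus strand) and fkh-4 in colour. No pooled summit lies in the 52152 bp around fkh-4.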

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

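No paired analysis was possible because the series has only 1 group. Read depth is not given in the sources used here, so what depth limits could not be measured. The 1189 peaks that enter the IDR set decide most counts. Alternatives with strict family names, with peaks matched in both replicates and without the 14-base element were chosen after seeing the data.

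Replicate overlap (50.1% to 73.6%) and promoter share (48.2% to 70.9%) stayed past their thresholds under every alternative run, with a promoter share of 56.3% and 60.1% without replicate 2 and without replicate 1. The rank correlation was 0.665 when summits had to lie within 50 bp, outside the interval of the main value. The share of peaks on X, 17.9%, passed the threshold only against the share of coding genes. Replicate 1's unmatched peaks differed from its matched ones by -6.16 percentage points in promoter share among the 594 strongest, where p was 0.178, and the cause was not tested.

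The number of gene lists past the threshold, 14, fell to 7 with the 594 strongest IDR peaks, to 9 with the narrower promoter window, to 8 against genes with any pooled peak and to 9 under circular shifts; the first 3 alternatives enter fewer bound genes or fewer genes, and the cause was not tested further. Calls for ribosomal proteins, heat shock proteins, translation factors, chemoreceptors, C-type lectins and F-box genes were kept under each of the 10 alternatives that could change them (11 for ribosomal proteins and chemoreceptors), with adjusted p of at most 0.0116. Body wall muscle kept 9 of 10, respiratory chain 7, nuclear hormone receptors 6, cell cycle 5, P450 and UGT genes 5, Wnt 4, and proteasome and neuropeptides 2. The bHLH genes were not past the threshold in the main test. They turned from an odds ratio below 1 to 3.32 with assignment to the nearest TSS (exact adjusted p = 0.0475). That assignment also counts peaks outside promoter windows.

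The number of motifs past the threshold, 17, fell to 10 with the 594 strongest peaks and to 11 against dinucleotide shuffles. Against shuffles, which remove the difference in base composition, 5 motifs that passed the threshold in at least 1 of the 2 tests turned direction, in points of summit minus shuffle: the forkhead core (0.841), the homeodomain site (2.103), MEF2 (1.18), the trans-splice acceptor (1.43) and the RFX site (-2.44). The AGGTCA site (-0.589) and the heat shock element (0.0841) also changed sign, past the threshold in neither test. GACGC, CTGCGTCT, both E-boxes, the C-rich site and GATA kept their calls under the 7 alternatives that could change them.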

Other observations

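Tests in this part on the SL2 RNA genes, coding exons, words of 10 bases, the 14-base element, promoter location, neighbours of respiratory chain, cell cycle and proteasome genes, and extra gene copies were chosen only after the result was seen. Among snRNA genes, 4 of 18 SL2 RNA genes (sls-2.1, sls-2.2, sls-2.4 and sls-2.8), whose product is spliced onto downstream genes of operons, had a peak within 200 bp (22.2%, 6.41 to 47.6, against 1.91% of coding genes), and 0 of 12 SL1 genes did (up to 26.5%). Of the peaks of replicate 1 unmatched in replicate 2, 46 of 413 (11.1%) lay in coding exons, against 13 of 776 matched ones (1.68%). Among the 594 strongest peaks of replicate 1 the shares were 3 of 157 (1.91%) and 8 of 437 (1.83%). For unmatched and matched peaks of replicate 2 they were 2.40% and 1.42% among the 1189 strongest. Among its 594 strongest they were 1.86% and 1.15%. Of the words of 10 bases, GAGACGCAGA was shared by the most summits, 90 peaks (7.57%) against 6 flanks centred 500 bp away, and it contains GACGC and, on the other strand, the whole of CTGCGTCT.

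A 14-base element, GTACTCCTCTCGGA, marked many of the strongest peaks. With at most 1 mismatch it lay within 100 bp of 71 IDR summits (5.97%, 4.69 to 7.47) and in 2 of the flanks 500 bp away, with a median distance of 27.5 bp from the summit. Peaks with it had a median signal of 158 against 79.2 for the others, and 11 of the 20 strongest had it, among them those at cux-7, thoc-5, lrpr-1, sco-1, ced-5 and cyn-10.

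Within 100 bp of the summits of these peaks, a median of 100% of the 36-base words occurred once in the genome. This argues against reads shared between the element's 428 copies as the account of most of these peaks. A median does not exclude it for the less unique peaks. Promoter location alone was tested on chromosomes where the word had not been chosen: promoter copies of the word from I, II and III had an IDR summit within 100 bp at 31 of 75 sites on IV, V and X (41.3%, random promoter positions at most 5.33%). The word from the latter, CCGAGAGGAGTACA, overlaps the first on the other strand and had one at 40 of 134 sites on I, II and III (29.85%, at most 5.97%), which argues against location alone. Copies outside promoter windows had a summit far less often than those inside, 3 of 212 (1.42%) against 73 of 216 (33.8%), and 68 of the 71 peaks (95.8%) lay in promoters, so a copy alone did not suffice; whether the 3 exceed chance stays open, since 1000 shifts gave 0.228% on average and 2.83% at most. No biological explanation was tested, since the design has 1 group and the control is not analysed here.

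The peaks at housekeeping promoters could come from neighbouring genes, gene density or open chromatin. Assignment of each peak to the nearest TSS left 21 of 81 ribosomal protein genes bound instead of 37 (25.9%, odds ratio 6.28, exact adjusted p = 1.71e-08). Neighbouring genes may thus account for part of that list's peaks, but the remaining share argues against them as the whole account. Lists matched on nearby gene starts reached at most 16.05% of genes bound against 45.7%, which argues against gene density for ribosomal protein genes. For respiratory chain, cell cycle and proteasome genes neighbours stay open, since with the nearest TSS their odds ratios fell to 1.47, 2.27 and 2.44 and all 3 calls were lost (exact adjusted p = 0.555, 0.209 and 0.213). Open promoters without sequence-specific binding also stay open, since the forkhead core differed by -3.16 percentage points between summit and flank at the 95 promoter peaks of the lists called higher (exact McNemar p = 0.607), and at peaks outside promoters it was not more frequent either (6.94% against 10.2%, p = 0.0929). No biological explanation was tested.

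The peak-free stretch around fkh-4 might reflect non-unique sequence, few genes or extra copies of the gene in the strain. Of the gap's 36-base words, 92.6% occur once in the genome, as do 92.1% over the nuclear genome, while 8 of the 10 widest pooled gaps had 66.1% or less. A wider gap on chromosome II, of 54291 bp, held 95.85% unique words and 13 coding TSS. The fkh-4 gap was thus not the only such stretch. Of 23918 overlapping windows matched on gene starts and GC content, 0.0251% had no pooled summit, with a median of 15 summits. The unique words and these windows argue against non-unique sequence and few genes for the fkh-4 gap. Extra copies stay open: 0.639% of the genome lies in pooled gaps as wide and neither replicate had a summit within 10 kb of fkh-4, but any cause of the gap would give these values. The plan had named extra copies only as able to raise the signal, and how they could remove peaks was not tested. Masking of the region during peak calling also stays open, since the sources used here do not describe that step. At unc-119, also carried as a rescue, the pooled list had 4.75 summits per 10 kb, above the genome mean of 2.99. That locus does not decide the question, since the copies of either gene were not counted. Coverage and the control, which would decide, are not analysed here, and no biological explanation was tested.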
